A study of Homo sapiens with 6 samples.

How the data were processed

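RNA sequencing was done on 6 HUDEP2 samples. Per the labels' protocols, RNA was extracted with Qiagen RNeasy, cDNA was amplified from a very small input with a SMARTer low-input kit, and NexteraXT libraries were read as single ends. The labels name 3 controls and 3 mutants, numbered within each group, and these names gave the groups. The deposited table holds raw counts per gene, which the authors made from the reads, per the labels and the submitters' processing notes. The notes name Trimmomatic 0.36, STAR 2.6.0c, Subread 1.6.1 with featureCounts, and the builds GRCh37.p13 and hg19; the order and settings of these steps, the annotation and the strand setting are not given in the sources used here. Because the kit does not mark strand, reads of a gene and its antisense partner cannot be told apart, and genes with near-identical copies can share reads. Columns were matched to samples by the sample names in the labels. The column of control 2 carries an added word after the sample name that the labels do not explain. Mitochondrially encoded genes were not analysed here.

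The table had 26364 gene names, of which 8858 had no counts. No row without a gene name had to be removed. Total counts per library lay between 18182357 and 20209639, so that a floor of 3 counts was 0.148 to 0.161 CPM in a library; floors and counting intervals cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Gene names were matched, through current and older symbols, to a RefSeq gene table of the assembly GRCh38.p14, which differs from the authors' build. It was used only for names, chromosome membership and gene order, and no coordinates are printed. A chromosome was found for 25044 names (95.0%). Of the gene list entries, 658 matched by current symbol, 33 by an older symbol and 20 not at all.

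The main comparison used edgeR 4.0.16 in R 4.3.3: filterByExpr with the group, which left 12074 genes, TMM factors, estimateDisp, a robust glmQLFit on all 6 libraries with the group as the only term, and glmQLFTest. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The common biological coefficient of variation was 0.351. CPM use the TMM-scaled library sizes, and log2 CPM a prior count of 2. The standard error of a log2 fold change is its absolute value divided by the square root of the F statistic. Where 1 group had 0 counts, a fold was computed against 3 counts over that group's 3 libraries and given as a lower bound, and with 1 to 3 counts the ratio was given with an exact 95% counting interval. Replicates were compared before use: the chi-square statistic per degree of freedom over genes was 25.1 or more in every pair of libraries, so none was taken for a duplicate; this does not show that libraries are independent.

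Fixed before the data were examined were the design, the alternatives, 29 gene lists and the rule for named genes. The rule named CDAN1, CDIN1, ASF1A, ASF1B, HBB, HBG1, HBG2, GATA1, KLF1, SLC4A1, TFRC and KIT in any case, and 1 gene that is not reported here. It then took the 6 genes in each direction with the largest change among those past the threshold, or, since fewer passed, the 6 with the smallest p. It also took up to 3 members of each list among those past the threshold, of which there were none, and passed over unnamed, non-coding and Y-linked genes. Any other gene named in the text was chosen after its values were seen. Lists with 3 or more tested genes, 26 of the 29, were tested with limma 3.58.1 on voom values, by camera with a preset inter-gene correlation of 0.01, adjusted over the lists; camera with an estimated correlation and fry stood beside it. Lymphocyte markers and stromal markers had too few tested genes.

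Chromosome medians were computed on autosomal genes with a mean log2 CPM above 3. Each gene's log2 CPM was set against the mean of the controls, or for a control against the other controls, and the median was taken per chromosome and in 6 bins of equal gene number in chromosome order. Segments named in the text were chosen after these medians were seen. The sex chromosomes were left out of this step.

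The alternatives fixed before the data were examined were RLE size factors, library totals only, globin genes left out, no low-count filter, a stricter filter (5 CPM in 3 libraries), DESeq2 1.42.0, limma voom, the replicate number as a block, the letter in the sample name as a covariate, an estimated correlation, fry, and each library left out in turn. Leaving out the genes of chromosome 18, the genes of 7 chromosomes with shifted segments (chromosome 19 was kept), or control 3 and mutant 2 together was added after seeing the data. The steps were tested on simulated data before use. For controls against mutants, counts were drawn from the real means, library sizes and dispersions, with 100 genes changed 4-fold and 100 changed 16-fold. Of the changed genes that were tested and estimated in the right direction, edgeR called 75.3% of the 4-fold and 91.8% of the 16-fold changes. Among 11806 genes tested, it called 10 unchanged genes. The simulated counts held no library that stood apart and no shifted chromosome blocks. These shares therefore do not give the power of the test in the real libraries. A second simulation for the same comparison shifted 1 list by 0.5 (log2). Camera on 11836 genes found that list with an adjusted p of 1.4e-27 (0.00494 with an estimated correlation), and no other list. Genes were drawn independently of each other, so this simulation could not show false list calls that arise when genes vary together. Chromosome medians over 8774 genes recovered a shift of -0.6 on chromosome 18 as -0.628 to -0.560, with no other autosome beyond 0.0653. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.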

Results

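The transcriptome of HUDEP2 cells, an immortalised human erythroid progenitor line, was profiled by RNA sequencing in 3 control libraries and 3 libraries labelled as codanin-1 (CDAN1) mutants. CDAN1 is mutated in congenital dyserythropoietic anemia type I, and the series asks what engineered mutations of this gene do in human erythroid cells. All libraries came from cells kept in an expansion medium that held dexamethasone, stem cell factor and erythropoietin. The total count per library lay between 18182357 and 20209639, and between 14361 and 14796 genes had at least 1 count. Globin genes took 1.76% of the counts in control 1 (95% Wilson interval 1.75 to 1.77) and 10.1% in mutant 2 (10.1 to 10.1), the lowest and highest shares of the 6 libraries. Pearson correlations of log2 CPM across genes, which are not independent replicates, ranged from 0.912 to 0.967 within groups and from 0.908 to 0.953 between groups. No pair of libraries agreed within sampling noise, so none was taken for a copy of another, and each counted as 1 replicate, as labelled. This does not show that they are independent. Mutants 1 and 3, the most alike pair (r = 0.967), shared shifted blocks of chromosomes 7 and 18. Controls 1 and 2, the next most alike pair (r = 0.963), shared shifted blocks of chromosome 8, and all mutants shared a lower level of chromosome 18. The labels do not say whether replicates were separate clones or cultures, and p-values measure the spread between these libraries only.

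The first question was whether the edited gene itself differed between the groups. CDAN1 transcript was measured at 35.3, 42.7 and 26.03 CPM in controls 1, 2 and 3 and at 19.6, 37.0 and 34.9 CPM in mutants 1, 2 and 3. The log2 fold change was -0.19 ± 0.29 (SE), with an edgeR adjusted p of 0.905, and it became 0.05 without mutant 1. The transcript level therefore neither separated the groups nor checked the labels; the kind of mutation is not given in the sources used here. Among genes tied to codanin-1, the histone chaperone ASF1A, which binds codanin-1, was lower in all mutants, at 154.6 ± 23.8 CPM against 221.1 ± 44.3 CPM (SD, n = 3 each; adjusted p = 0.475). Its log2 fold change was -0.52 ± 0.18 (SE), and ASF1A lies on chromosome 6, where genes as a whole were lower in mutant 2. Its paralog ASF1B had a log2 fold change of 0.01 ± 0.16 (SE; adjusted p = 0.994), with a sign that changed between settings. CDIN1, the other gene mutated in this anemia, listed as C15orf41, had 15.7 ± 2.12 CPM in the mutants and 10.9 ± 3.37 CPM in the controls (SD, n = 3 each; adjusted p = 0.662). Of the 11 tested genes in the list of codanin-1 partners and congenital dyserythropoietic anemia genes, 4 had positive and 7 negative fold changes, and the list did not pass (camera adjusted p = 0.422).

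Genes that differed most steadily between the groups included several that were present in one group and nearly absent in the other. The atypical cadherin FAT1 and the receptor phosphatase PTPRK had 0 counts in the 3 controls and means of 5.37 ± 2.24 and 18.3 ± 12.1 CPM in the mutants (SD, n = 3). They were at least 105-fold and 358-fold higher, against a floor of 3 counts over the control group. EPB41L3, a membrane skeleton protein of the band 4.1 family, was likewise at 0 in the controls and at 13.5 ± 7.36 CPM in the mutants, at least 263-fold higher. In the other direction, FERMT1, an integrin activator, had 543 counts over the controls and 1 over the mutants, a ratio of 526 (95% counting interval 93.9 to 20800). ARHGAP9 had 810 counts against 3, a ratio of 261 (89.1 to 1270). More graded differences were seen for PAM, a peptide-amidating enzyme, with a log2 fold change of 1.26 ± 0.15 (SE), the protease subunit CAPN2 with 1.31 ± 0.18 and the pentraxin NPTX1 with 1.45 ± 0.21. FAM178B was lower by a log2 fold change of -1.61 ± 0.17, the spectrin SPTBN1 by -3.11 ± 0.37, the transglutaminase TGM2 by -0.83 ± 0.10 and TYMS, the thymidylate synthase of DNA synthesis, by -1.50 ± 0.19. These 12 genes had the smallest p in each direction; in each, all mutants lay on one side of all controls.

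None of these genes passed the test: edgeR's quasi-likelihood test called 0 genes higher and 0 lower among 12074 tested, and the lowest adjusted p was 0.104. At an unadjusted p under 0.05, 481 genes were higher and 559 lower, 1040 in all, and the split of controls 1 and 2 with mutant 3 against the rest gave more, 1066. DESeq2 called 100 higher and 189 lower, and limma voom 0 in either direction. The DESeq2 calls held every gene of the preceding paragraph, with adjusted p from 3.43e-13 (PTPRK) to 5.82e-07 (NPTX1). FERMT1 passed in 7 of 18 alternative settings. In 884 genes (7.32%) all mutants lay above all controls and in 894 (7.40%) below, where chance gives 5% in each direction. The edgeR count depended on single libraries: it became 30 higher and 59 lower without control 3, 3 and 24 without mutant 2, and 1 and 0 without control 2. With control 3 and mutant 2 both left out, a setting chosen after seeing the data, 137 genes were called higher and 184 lower. Many of these calls lay on 2 chromosomes: 41 of the 89 autosomal and X-linked genes called without control 3 were on chromosome 8, and 68 of the 287 called by DESeq2 were on chromosome 18.

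**Figure D1:**
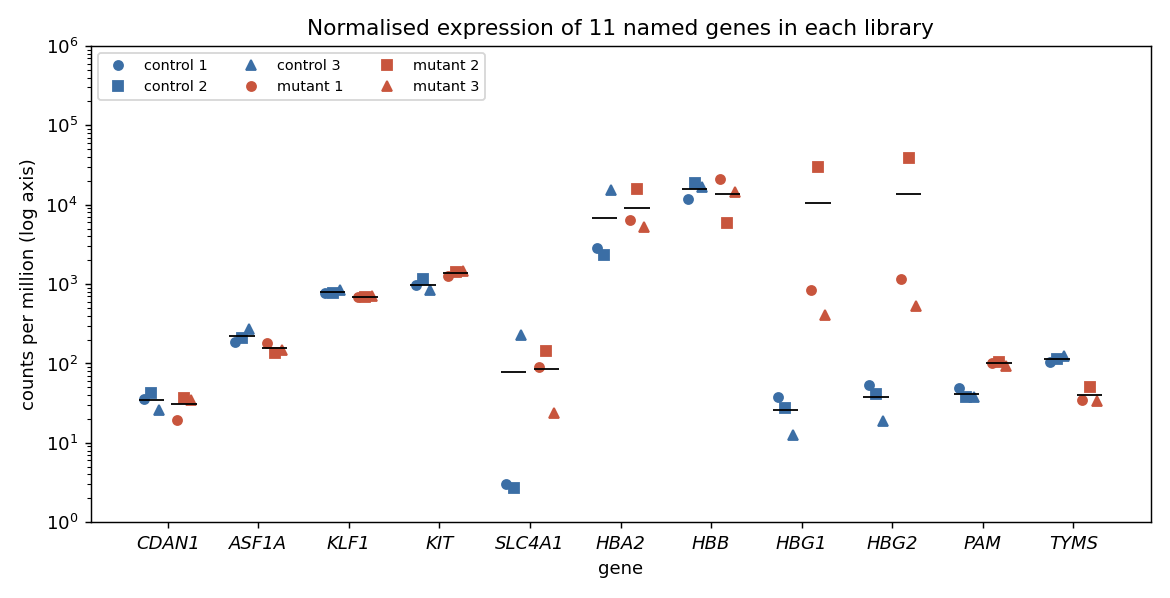
Normalised expression of 11 genes in each library, in CPM on a log axis; blue marks are controls, red marks are mutants, mark shapes give the replicate number and black lines are group means. HBG1 and HBG2 lie higher in every mutant than in every control, with mutant 2 at 29950 CPM for HBG1, while CDAN1, HBB, HBA2 and SLC4A1 overlap between the groups.

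Fetal globin transcripts were higher in each mutant than in each control, to very different extents. The gamma-globin genes HBG1 and HBG2 are near-identical copies between which reads can be split, so their sum is given: 92.0, 68.5 and 31.5 CPM in controls 1, 2 and 3, and 2025, 68900 and 931 CPM in mutants 1, 2 and 3. The lowest mutant sum was 10.1 times the highest control sum, and mutant 2 was 74.0 times mutant 3. Gamma-globin made up 0.773%, 0.368% and 0.191% of the HBB and gamma-globin counts in controls 1, 2 and 3, with 95% Wilson intervals of 0.739 to 0.809, 0.348 to 0.388 and 0.176 to 0.207. In mutants 1, 2 and 3 the share was 8.85% (8.77 to 8.94), 92.1% (92.0 to 92.1) and 6.13% (6.04 to 6.22). The intervals cover counting error only. With this spread between mutants, the log2 fold changes of 8.64 ± 2.10 for HBG1 and 8.48 ± 2.07 for HBG2 (SE) did not pass (edgeR adjusted p = 0.346 each). They became 4.59 and 4.48 without mutant 2 (adjusted p = 0.107 each), and exact permutation of 3 against 3 libraries cannot give a two-sided p below 0.1. Adult beta-globin (HBB) was at 15620 ± 3459 CPM in controls and 13680 ± 7469 CPM in mutants (SD, n = 3 each; adjusted p = 0.938). It was lowest in mutant 2, at 5939 CPM, and its log2 fold change of -0.19 became 0.17 without that library. Of the 11 globin and globin chaperone genes tested, 9 had positive fold changes, and 2, the gamma-globin genes, passed when adjusted over the list alone. The list did not pass (camera adjusted p = 0.242), although it did without control 3 (0.0177). HBB and the gamma-globin genes lie in a part of chromosome 11 where genes as a whole were at -0.99 in control 3 against the other 5 libraries (log2, 161 genes).

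Among the erythroid identity genes given here, GATA1, KLF1 and TFRC had small fold changes. The master regulator GATA1 had a log2 fold change of -0.09 ± 0.12 (SE; adjusted p = 0.890), which turned to 0.01 without control 3. The globin activator KLF1 was lower in all mutants, at 690.5 ± 12.5 CPM against 794.0 ± 39.7 CPM in controls (SD, n = 3 each; adjusted p = 0.619). The transferrin receptor TFRC had a log2 fold change of 0.11 ± 0.15 (SE; adjusted p = 0.888). KIT, the stem cell factor receptor, was higher in all mutants, with a log2 fold change of 0.48 ± 0.14 (SE; edgeR adjusted p = 0.424). The anion exchanger SLC4A1, or band 3, followed no group: controls 1, 2 and 3 had 3.06, 2.74 and 229 CPM and mutants 1, 2 and 3 had 90.0, 144 and 23.6 CPM. Its log2 fold change of 0.13 ± 1.65 (SE; adjusted p = 0.994) turned negative without control 1, control 2 or mutant 2, to -0.45 at the lowest, and was 4.88 without control 3.

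Red cell membrane and surface protein genes were called higher as a list (camera adjusted p = 0.0324), with 19 of 27 tested members positive and 5 higher and 2 lower at an unadjusted p under 0.05. The list's call was lost with an estimated correlation (adjusted p = 0.995), and also without control 1 (0.581), control 2 (0.1), mutant 1 (0.109) or mutant 2 (0.115). Examples among members with a small p, chosen after their values were seen, were the urea transporter SLC14A1 with a log2 fold change of -2.15, GYPE with 0.69 and the acetylcholinesterase ACHE with 1.40. SLC14A1 lies on chromosome 18 and was the only member that passed when adjusted over the list alone. Control 3 stood apart here, with a list median 0.51 above the mean of controls 1 and 2 on the log2 scale. Against the mean of the controls, list medians were -0.305, -0.106 and 0.339 in controls 1, 2 and 3. They were 0.257, 0.253 and 0.151 in mutants 1, 2 and 3, so control 3 lay above every mutant.

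Cholesterol synthesis genes were called higher as a list (camera adjusted p = 0.0324): 16 of 24 were positive, and 7 lay higher in all mutants than in all controls. The call was lost with an estimated correlation (adjusted p = 0.995) and without control 1 (0.116), mutant 1 (0.0617) or mutant 2 (0.194). Examples, again chosen after their values were seen, were the sterol reductase TM7SF2 with 0.54, the cholesterol carrier STARD4 with 0.68 and the desaturase SC5D with 0.30, while SQLE, a rate-limiting monooxygenase on chromosome 8, had -0.40. DNA replication genes were called lower (camera adjusted p = 0.0324), with 31 of 41 negative and a median log2 fold change of -0.10. This call was lost with an estimated correlation (adjusted p = 0.995), without control 3 (0.324) and without mutant 2 (0.373), and with both left out the direction turned (0.960). It was also lost without the genes of 7 chromosomes with shifted segments (0.123). The 3 members with the smallest p lay on such chromosomes: TYMS on 18, CCNE2, the cyclin E2 gene, on 8 and MCM3, a subunit of the replicative helicase, on 6, with log2 fold changes of -1.50, -0.59 and -0.45. Of the DNA replication genes, 1 passed when adjusted over the list alone, and no cholesterol synthesis gene did. None of the 3 list calls held with an estimated correlation or with fry.

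**Figure D2:**
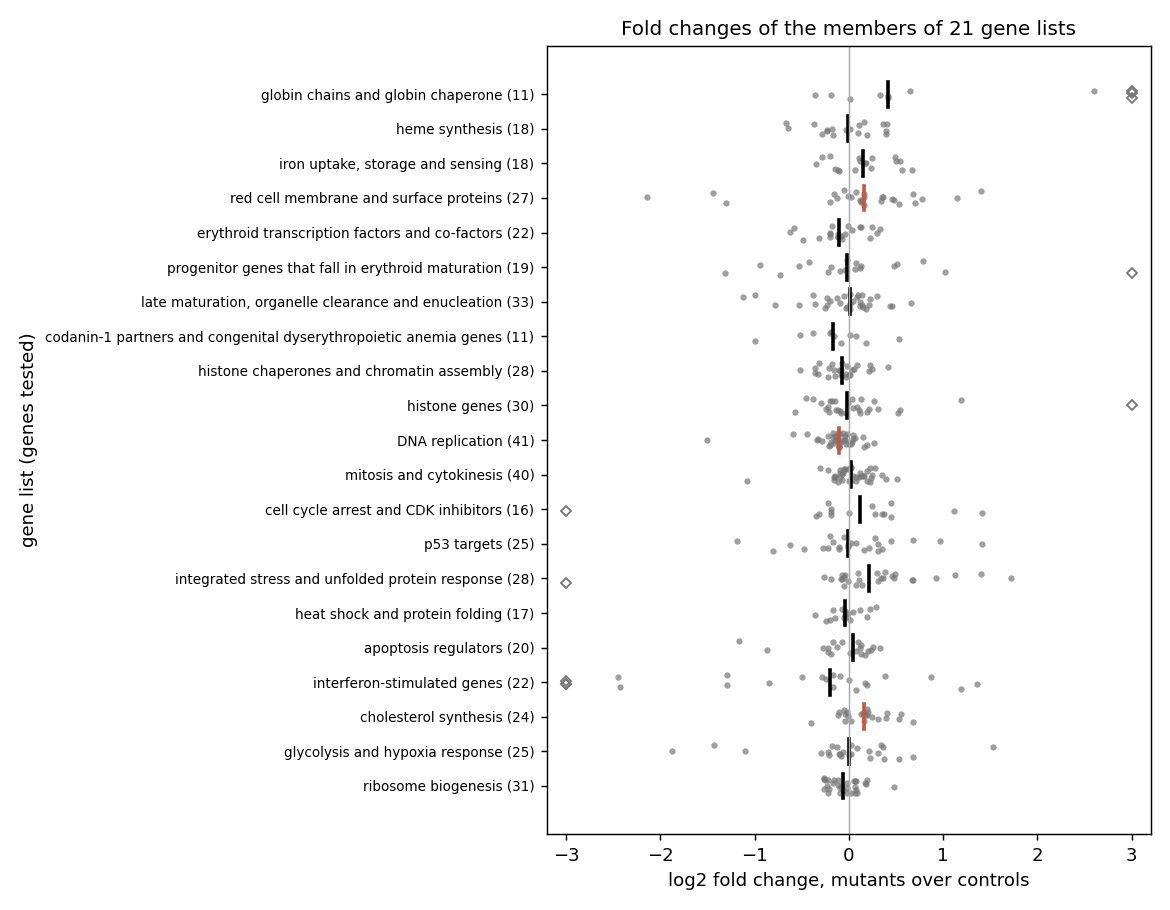
Log2 fold changes, mutants over controls, of the tested members of 21 biological gene lists, with the number tested in brackets; each grey point is a gene, open diamonds at 3 and -3 are genes beyond the axis, and vertical bars are list medians. Red bars mark the cholesterol synthesis, red cell membrane and DNA replication lists, with camera adjusted p of 0.0324 each and medians of 0.16, 0.16 and -0.10.

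The remaining lists did not pass. The integrated stress and unfolded protein response came closest, with 18 of 28 positive (camera adjusted p = 0.0734). Its members with the smallest p, HERPUD1 and SEL1L, both parts of endoplasmic reticulum degradation, had log2 fold changes of 0.48 and 0.34. Positive fold changes were found in 12 of 18 iron handling genes (adjusted p = 0.303), 9 of 18 heme synthesis genes (0.992), 7 of 22 erythroid transcription factors (0.596), 9 of 19 progenitor genes (0.992) and 18 of 33 late maturation genes (0.992). Histone chaperones were positive in 9 of 28 (0.303), histone genes in 14 of 30 (0.596), mitosis genes in 22 of 40 (0.855), cell cycle arrest genes in 8 of 16 (0.840) and p53 targets in 12 of 25 (0.992). Heat shock genes were positive in 6 of 17 (0.840), apoptosis regulators in 11 of 20 (0.944), interferon-stimulated genes in 8 of 22 (0.578), glycolysis and hypoxia genes in 13 of 25 (0.840), and ribosome biogenesis genes in 12 of 31 (0.585). Ribosomal protein genes were positive in 16 of 39 (0.578) and immediate early genes in 8 of 17 (0.992). Adjusted over the list alone, the progenitor gene IGF2BP3, on chromosome 7, and the late maturation gene CAT, for catalase, on chromosome 11, passed as higher. The late maturation genes CA1 and CA2, on chromosome 8, and the mitosis gene NDC80, on chromosome 18, passed as lower. No other gene of these remaining lists passed. Each of these chromosomes held a segment that was shifted in some libraries. The sign of the mean, the median and the test were not alike for the progenitor, late maturation, histone, cell cycle arrest, p53, apoptosis and glycolysis lists.

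No tested marker list of another blood cell type passed. Of the megakaryocyte markers, 4 could be tested (camera adjusted p = 0.242), and of the granulocyte and monocyte markers 3 (0.861). Of the mast cell and basophil markers, 8 were tested (0.992), 2 with positive and 6 with negative fold changes. Among these 8, PRG2, the eosinophil major basic protein gene, passed as higher when adjusted over the list alone, while MS4A2 had a log2 fold change of -2.21. The megakaryocyte tubulin TUBB1 averaged 19.4 ± 7.73 CPM in mutants and 5.43 ± 3.595 CPM in controls (SD, n = 3 each; edgeR adjusted p = 0.428). The mast cell tryptase TPSAB1 averaged 1670 CPM in controls and 1470 CPM in mutants. No lymphocyte marker exceeded 0.330 CPM in any library, and of the stromal markers only FBN1 exceeded 1 CPM, with means of 35.1 CPM in controls and 18.4 CPM in mutants.

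Genes of chromosome 18 were lower together in every mutant. Of 150 tested, 138 had negative fold changes, and 101 made up 18.1% of all genes lower at an unadjusted p under 0.05, while the chromosome held 1.24% of tested genes (Fisher's exact test across genes, two-sided, odds ratio 51.6, p = 2.49e-100). Genes are not independent replicates in that test. Relative to the mean of the controls, the chromosome's median was -0.72, -0.58 and -0.68 on the log2 scale in mutants 1, 2 and 3. TYMS, SLC14A1, the heme synthesis enzyme FECH, with a log2 fold change of -0.67, and the phosphatidate phosphatase LPIN2, with -0.995, lie there; EPB41L3, which was higher, does too. Other segments differed in single libraries or pairs of them. In mutant 2, chromosome 6 was at -0.58 against the other 5 libraries and chromosome 13 at 0.53 (407 and 148 genes). On chromosome 8, controls 1 and 2 were 0.96 above the other 4 libraries in bins 4 and 5 of the chromosome's 6 bins of genes (98 genes). This segment holds the carbonic anhydrase genes CA1 and CA2 and CCNE2. CA1 averaged 9088 CPM in mutants and 19860 CPM in controls, and CA2 1214 and 2429 CPM (edgeR adjusted p = 0.320 and 0.186).

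**Figure D3:**
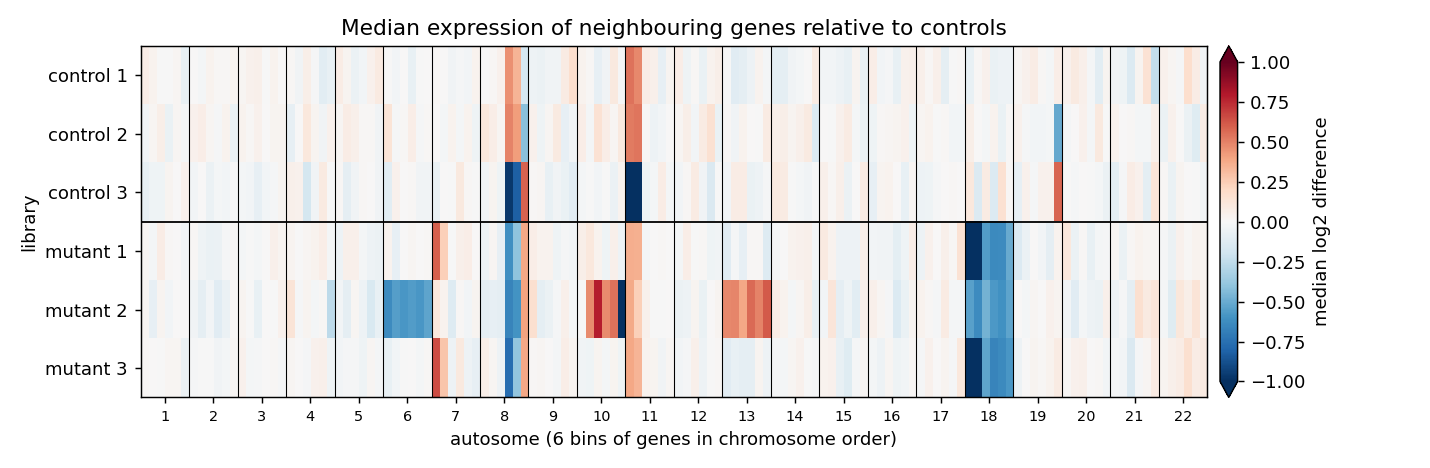
Median log2 difference of expressed genes in 132 bins, 6 per autosome in chromosome order, for each library; mutants are set against the mean of the 3 controls and each control against the mean of the other 2, red is higher, blue is lower and colours saturate at 1 and -1. Chromosome 18 is blue in the 3 mutants, darkest in the first 2 bins of mutants 1 and 3, and chromosomes 6, 10 and 13 stand out in mutant 2.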

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

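The settings that left out chromosomes, or control 3 and mutant 2 together, were chosen after seeing the data; the others were planned. Genes called higher and lower by edgeR stayed at 0 and 0 with RLE factors, library totals, globins left out, limma voom, the name letter and chromosome 18 left out. They were 2 and 4 with no low-count filter, 0 and 1 with the stricter filter and without chromosomes 6, 7, 8, 10, 11, 13 and 18, 100 and 189 with DESeq2, and 137 and 184 without control 3 and mutant 2. Leaving out 1 library gave 0 to 30 higher and 0 to 59 lower. Of 287 autosomal and X-linked genes called by DESeq2, 37 were among the 89 called without control 3. Lists called higher, 2 in the main test, were 0 with no filter, 4 without control 3 and mutant 2, 0 with an estimated correlation or fry, and 0 to 4 with 1 library left out. Lists called lower, 1 in the main test, were 2 with the name letter or without control 3 and mutant 2, and 0 with an estimated correlation, with fry or without the 7 chromosomes. Fewer genes or libraries entered the settings that left some out; otherwise the cause was not tested.

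By adjusted p, the red cell membrane list had 0.0735 with no filter, 0.995 with an estimated correlation, 0.975 with fry and 3.16e-05 to 0.581 with 1 library left out. Cholesterol synthesis had 0.0559, 0.995, 0.814 and 0.00683 to 0.194 in these settings, and 0.171 without control 3 and mutant 2. DNA replication had 0.995 with an estimated correlation, 0.939 with fry, 0.123 without the 7 chromosomes and 0.00375 to 0.373 with 1 library left out; without control 3 and mutant 2 it turned upward (0.960). Lists that passed only in some settings were globins (0.00382 with the name letter, 0.000458 without control 3 and mutant 2, 0.0177 to 0.549 with 1 library left out), integrated stress (0.0497 with the stricter filter, 0.00243 and 0.0177 to 0.491), mitosis (0.00243 and 0.0489 to 0.887), ribosome biogenesis (0.0268 with the name letter, 0.0144 and 0.0177 to 0.736) and ribosomal proteins (0.00115 and 0.0489 to 0.882). Of 464 list alternatives, 428 stayed on their side of the threshold, 20 lost and 15 gained a call and 1 reversed; 57 sign changes fell on lists with no call.

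Of 435 alternatives for named genes, 378 kept their side of the threshold and sign, 47 gained a call and 10 changed sign, none of them called. The CDAN1 log2 fold change ranged from -0.36 to 0.051 with 1 library left out, the ASF1B log2 fold change from -0.13 to 0.13 (-0.022 with the name letter), the HBB log2 fold change from -0.63 to 0.17 (0.21 without control 3 and mutant 2), the HBG1 log2 fold change from 4.59 to 9.20 (6.51 with limma voom, 6.15 with the replicate block, 4.25 without control 3 and mutant 2), the HBG2 log2 fold change from 4.48 to 9.04 (6.37, 5.99 and 4.17 in these settings), the FERMT1 log2 fold change from -10.48 to -8.12, the ARHGAP9 log2 fold change from -8.71 to -7.34, the PTPRK log2 fold change from 10.8 to 11.81, the GATA1 log2 fold change from -0.15 to 0.011 and the SLC4A1 log2 fold change from -0.45 to 4.88. No scaling moved the median of all genes by over 0.1.

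The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at 0.00837, -0.0756 and -0.177. With the replicate block, 0 genes were called higher and 0 lower, the red cell membrane list had an adjusted p of 0.0676 and the globin list of 0.0284, and the cholesterol synthesis and DNA replication lists had 0.0284 each. Depth limits genes near 3 counts per library, 0.148 to 0.161 CPM.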

Other observations

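The tests of gamma-globin read sharing, of mutant 2 alone, of a mislabelled control 3, of chromosome segments in control 3, of library scaling, of a codanin-1 effect on chromosome 18 and of all-or-none genes were chosen after the values were seen, as were the genes named here; the others were fixed before their result was seen. Some genes were all or none. With on defined as at least 2 CPM and off as at most 3 counts in a library, 102 genes were on in at least 1 library, off in at least 1 and between these levels in none, and 6 of them divided controls from mutants. FAT1, PTPRK, EPB41L3 and STX11 were on only in the mutants, and ARHGAP9 and FERMT1 only in the controls. Of the 10 ways to split the libraries into 3 and 3, 1, the real one, gave as many as 6, and the highest other gave 1; 10 splits are too few for a share under 0.05. More genes set single libraries apart: 19 genes divided control 3, 18 control 2 and 15 mutant 2 from the other 5 libraries, and 11 divided controls 1 and 2 from the other 4. The phosphatase PTPN6 averaged 1.56 CPM in mutants and 45.7 CPM in controls, and the kinase FES 1.34 and 21.5 CPM. Neither passed in the main test (edgeR adjusted p = 0.120 each). DESeq2 called both lower (adjusted p = 2.79e-18 and 7.49e-12), and so did edgeR without control 3 (0.0194 and 0.00509).

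Glycolysis genes differed in direction, none of them past the threshold in the main edgeR test. The pyruvate kinase PKM averaged 94.0 CPM in mutants and 344.3 CPM in controls and the hexokinase HK2 21.6 and 46.4 CPM. The neuronal enolase ENO2 averaged 21.1 and 7.29 CPM (edgeR adjusted p = 0.428, 0.335 and 0.305 in this order). DESeq2 called HK2 lower and ENO2 higher (adjusted p = 0.0123 and 0.00448). LIN28B, an RNA-binding protein of fetal cells, was at 30.6, 6.74 and 0.157 CPM in mutants 1, 2 and 3 and at most 1.499 CPM in controls, and IGF2BP1, another RNA-binding protein of fetal cells, was at 62.1 and 52.5 CPM in controls 1 and 2 and 69.6 CPM in mutant 2 but at most 1.48 CPM in the others. IGF2BP3 averaged 103.4 CPM in mutants and 59.8 CPM in controls (adjusted p = 0.251). The interferon-induced genes IFIT2 and IFIT3 were at most 1.10 CPM in mutants and at 16.3 and 29.2 CPM in control 3. The cell cycle kinase CDK6 had 69.1 and 80.5 CPM in controls 1 and 3, 0 counts in control 2 and 12 counts over the mutants.

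Expression along chromosomes differed between libraries in blocks whose sizes lay near simple copy ratios. A change from 3 copies to 2 would give -0.585 on the log2 scale, from 2 to 3 0.585, from 2 to 1 -1 and from 3 to 1 -1.58. The medians were -0.58 over bins 3 to 6 of chromosome 18 in the 3 mutants (74 genes), and -1.55 over bins 1 and 2 in mutants 1 and 3 (37 genes), where mutant 2 had -0.58. Bin 1 of chromosome 7 was at 0.58 in mutants 1 and 3 (63 genes), which were also the most alike pair of libraries (r = 0.967). Whether libraries that share such blocks are independent of each other was not tested. Mutant 2 had 0.56 over bins 2 to 5 of chromosome 10 (208 genes) and -0.996 in bin 6 (52 genes), where the heme synthesis gene UROS lies. Controls 1 and 2 stood 0.96 above the other 4 libraries in bins 4 and 5 of chromosome 8 and at -0.58 in bin 6 (49 genes), and control 3 was at -0.99 over bins 1 and 2 of chromosome 11. Bin 6 of chromosome 19 was at -0.51 in control 2 and 0.58 in control 3, each against the other controls. Each was set against a mean that held the other, so both values are larger than against all controls. They cannot be set beside the copy ratios. Against the mean of the controls, mutants 1, 2 and 3 were at 0.0315, 0.0256 and 0.0844 in this bin.

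The lower level of chromosome 18 genes in all mutants was weighed first. Library scaling or depth was argued against, because a factor per library moves all chromosomes alike, and chromosome 18 lay at least 0.565 below the other autosomes in each mutant (difference nearest to 0, -0.565). Fewer copies of chromosome 18 in the mutant cells may account for the pattern: the highest of the 18 bin medians in the mutants was -0.476, so the level was lower along the whole length. An effect of the codanin-1 mutations on this chromosome's genes cannot be told apart from a copy change carried by the same cells. The lower level was found in 3 of 3 mutants and no control. It was picked for following the groups, so this count tests neither. DNA was not analysed here.

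For the higher gamma-globin transcripts, reads shared between HBG1 and HBG2 were argued against, since the sum of both was 10.1 times higher in the lowest mutant than in the highest control, and so was mutant 2 alone, since the same 10.1-fold gap held between the lower of mutants 1 and 3 and the controls. A lower level of the fetal globin repressor MYB could contribute. Of BCL11A, MYB and ZBTB7A, 1 of 3, MYB, was lower in all mutants. It was at 216.3 ± 13.8 against 312.0 ± 48.3 CPM (SD, n = 3 each, edgeR adjusted p = 0.339). As 7.4% of all tested genes lay lower in all mutants, 1 of 3 is weak evidence. BCL11A overlapped between the groups: mutant 2, at 37.96 CPM, lay above controls 1 and 2, and control 3 was at 81.06 CPM. ZBTB7A overlapped too, with 33.23 CPM in mutant 2 and 30.33 CPM in control 2. MYB lies on chromosome 6, lower as a whole in mutant 2, and its level of 204, 214 and 231 CPM in mutants 1, 2 and 3 did not follow their gamma-globin levels. An effect of the codanin-1 mutations and a difference between cell clones stay open, both untested.

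Control 3 lay apart from controls 1 and 2, with correlations of 0.936 and 0.912 against 0.963 between those. A mislabelled mutant that carries the lower chromosome 18 was argued against, because control 3's chromosome 18 median was 0.0635 relative to the other controls. A mutant without that lower level would pass unseen, since the level was picked from the labelled groups. In bins 4 and 5 of chromosome 8, controls 1 and 2 lay 0.96 above control 3 and the mutants. Of the all-or-none genes, 11 divided controls 1 and 2 from all other libraries, and 6 divided controls from mutants. The levels of genes on shifted chromosome segments were argued against as the whole cause. Genes of chromosomes 6, 7, 8, 10, 11, 13, 18, 19 and the sex chromosomes were left out. The higher correlation of control 3 with control 1 or 2 was then 0.938, against 0.967 between those. On each of the 14 autosomes left it lay below theirs, by 0.0131 to 0.0508. Effects of such segments on genes elsewhere were not tested. Cells further along erythroid maturation may account for part of the distance of control 3, as the red cell membrane list had a median 0.509 higher and the progenitor list one of -0.26. Heme synthesis (0.44) and late maturation genes (0.282) were higher too, but so were DNA replication (0.126) and mitosis genes (0.152). The immediate early and handling stress list moved as far as the membrane list (0.522, 14 of 17 above 0). The 4 tested megakaryocyte markers had a median of 2.33. Interferon-stimulated genes of control 3 were also higher (median 0.90, 17 of 22 above 0). No explanation of these other shifts was tested.

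The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. For genes past the threshold they allow no comparison, since the real split gave 0 higher and 0 lower, which each of the 10 splits reaches whatever it gives (highest other 1). At an unadjusted p under 0.05 the real split gave 1040 genes and the highest other 1066. For gene lists, with the larger direction of each other split counted, 9 of 10 gave as many as the 2 called higher and 10 as many as the 1 called lower, with 9 the highest other in both cases. The split of controls 1 and 2 with mutant 3 against the rest gave those 1066 genes in both directions together, and 9 lists in one direction and 4 in the other, which points to a structure of the samples that the groups do not describe.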
